A study of Danio rerio with 7 samples.

How the data were processed

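Polyadenylated RNA of gata1-positive cells from zebrafish embryos at 40 hours post fertilization was extracted with a microprep kit and made into low-input libraries, per the labels' protocols. The deposited table holds raw counts per Ensembl gene, one column for each of the 7 libraries and one row for each of 32105 genes. The submitters' processing notes name Trim Galore, STAR 2.4.2a, Picard, Cufflinks 2.2.1 and DESeq2 and the genome build GRCz10, without roles or order. The counting program, its strand setting and the annotation release are not given in the sources used here, so overlapping and antisense genes may share reads. The columns were matched to samples by their titles, and 0 columns belonged to other samples.

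Symbols came from a table of Ensembl IDs and names: 26269 of 32105 IDs had a symbol and 5836 had none. Many symbols are in human style, in capitals, and 4301 IDs share theirs with another ID, so a paralog suffix is not resolved and such genes are given with their ID. Of the 1273 symbols in the gene lists, 1177 were matched, some only after a paralog suffix was dropped. The ddx41 transcript is not analysed here. Pairs of libraries within a group differed by more than counting noise (chi-square per degree of freedom 17.5 to 64.4), so none was counted as a duplicate. The most abundant rows were 2 IDs without a symbol, which took 17.4% of the counts in siblings and 21.0% in mutants on average.

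Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr by group (minimum count 10, total 15), which left 18565 genes, and libraries were scaled by TMM. Mutants were compared with siblings by the quasi-likelihood F-test (glmQLFit and glmQLFTest, defaults) with Benjamini-Hochberg adjustment at 0.05 and no block. Values per library are CPM with TMM scaling, means carry an SD, and folds come from the fitted log2 fold changes. Totals of 11814324 to 14363255 counts set the counting precision, and the common biological coefficient of variation was 0.377. Gene lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over 33 lists. Camera at an estimated correlation, which also uses far fewer degrees of freedom, and fry were run beside it. Shares of counts were compared by exact permutation tests over 35 splits, whose smallest two-sided p is 0.0286.

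The groups, tests, gene lists, alternatives and the rule for named genes were set before the data were examined. The rule named ddx41. It also named the 6 largest changes per direction among called genes with a symbol, a mean of at least 5 CPM and groups that do not overlap, then the 3 members with the smallest p of each list called by camera and the 1 such member of every other list. It gave 66 genes, of which 1, with its gene list, is not reported here. The alternatives were other scalings, other filters, DESeq2 1.42.0, limma-voom with and without sample weights, robust fitting, each library left out, the replicate number as a block, and other list tests. Alternatives and 6 further gene lists chosen after seeing the data are named as such in the closing section.

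The steps were tested on simulated data made from the means, dispersions and library sizes of the mutant and sibling libraries over 18565 genes. Of 100 genes changed 2-fold, 38% were recovered, and of 100 changed 4-fold, 96% were recovered. The changed genes were drawn from those with a mean of at least 5 CPM, so recovery of less abundant genes was not measured. Of all 141 calls, 4.96% were false. With the spliceosome list raised by 1.5-fold, camera called it and none of the other 32 lists. The simulated genes varied independently, which real genes do not.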

Results

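Polyadenylated RNA from gata1-positive erythroid cells of zebrafish embryos was sequenced at 40 hours post fertilization, in 4 sibling libraries (replicates 1, 3, 4 and 5) and 3 ddx41 mutant libraries (replicates 2, 3 and 4). The gata1 gene encodes a transcription factor of the red cell lineage, and ddx41 encodes a DEAD-box RNA helicase. Total counts ran from 11814324 in ddx41 mutant replicate 2 to 14363255 in ddx41 mutant replicate 4. The siblings had 23340 genes with a count on average and the mutants 23820. The first principal component of log2 CPM held 40.7% of the variance and separated the groups, and the second held 17.3% and placed sibling replicate 5 and ddx41 mutant replicate 4 at one end. Spearman's rho across genes lay between 0.937 and 0.944 among siblings, between 0.919 and 0.936 among mutants, and between 0.871 and 0.899 across the groups. The ddx41 transcript was not analysed here, so the labels were not checked against the level of the targeted gene.

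The comparison of mutants with siblings asks which transcripts differ in erythroid cells that carry the ddx41 mutation. Many spliceosome transcripts (58 of 108) and most transcripts of the mitochondrial genome (10 of 13) were higher in the mutants, and many mitotic genes (23 of 47) and 6 of 23 erythroid regulators were lower. These 4 lists passed camera with its preset correlation, and none passed with an estimated correlation (adjusted p 0.539, 0.539, 0.673 and 0.673). With fry the adjusted p values were 0.0101, 0.0151, 0.051 and 0.0786. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05, 3073 of 18565 tested genes (16.6%) differed, 1646 of them higher and 1427 lower in the mutants. Of these, 1222 were higher and 980 were lower by at least 2-fold. The groups did not overlap at 2879 of the called genes. Over all tested genes the groups did not overlap at 27.5%, where chance gives 5.71%. Without ddx41 mutant replicate 2 the number of called genes was 1888. The labels do not say whether the libraries came from separate clutches, so the p-values measure the spread between these libraries.

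The largest changes were ranked among called genes with a symbol, a mean of at least 5 CPM and groups that do not overlap. The 6 largest rises there were led by si:ch73-65n21.1, which rose from 0.0954 ± 0.147 CPM in siblings (SD, n = 4) to 13.1 ± 0.777 CPM in mutants (SD, n = 3). PDE6D, which encodes a prenyl-binding chaperone, rose 60.1-fold, from 0.640 to 39.1 CPM. The uncharacterized gene si:dkey-204l11.1 rose 39.4-fold to 127.6 CPM. MPPED1 rose 28.2-fold, and tymp, the thymidine phosphorylase gene, rose 27.0-fold. Transcripts of ice1, a subunit of a complex that transcribes small nuclear RNA genes, rose 23.4-fold, from 19.6 ± 4.09 to 459.3 ± 46.2 CPM (edgeR adjusted p = 1.6e-08). Among the 6 largest falls, the chemokine gene ccl34b.1 was 43.7-fold lower and ccl35.1 was 21.3-fold lower in mutants. The uncharacterized genes si:ch211-103n10.5 and si:dkey-235h8.1 were 25.2-fold and 14.7-fold lower. CH25H, the cholesterol 25-hydroxylase gene, was 14-fold lower, and IFFO1 (ENSDARG00000062976, 1 of 2 tested IDs with that symbol) was 11.8-fold lower. All 12 passed edgeR's test, with adjusted p values from 1.6e-08 to 0.00196.

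Of the 108 tested spliceosome genes, 58 rose, 2 fell and 48 did not pass the test, and 66 rose and 3 fell when adjusted over the list alone. The median log2 fold change was 0.87. SNRPD2, a core protein of the spliceosomal snRNPs, rose 13.3-fold, from 19.4 ± 3.2 CPM (SD, n = 4) to 259.4 ± 37.8 CPM (SD, n = 3). XAB2, a component of the Prp19-associated complex, rose 10.2-fold to 142.2 ± 16.6 CPM, and PRPF3, of the U4/U6 snRNP, rose 8.48-fold to 390.0 ± 66.5 CPM. The edgeR adjusted p values of these 3 genes were 4.4e-08, 5.49e-08 and 1.15e-07. The camera adjusted p of the list was 9.06e-50 with the preset correlation, and the adjusted p was 0.539 with an estimated correlation. The lists of ribosome biogenesis, ribosomal proteins, nonsense-mediated decay and R-loops were not compared with the spliceosome list directly. Among them, 10 of 71 ribosome biogenesis genes rose and 1 fell, led by DDX56 (4-fold higher), and 2 of 81 ribosomal protein genes rose and 2 fell, with RPL22 1.99-fold higher (edgeR adjusted p = 0.0523 without ddx41 mutant replicate 2). The number of ribosome biogenesis genes that rose was 2 without ddx41 mutant replicate 2, 3 without sibling replicate 4 and 6 without sibling replicate 5, and the number of ribosomal protein genes that rose was 9 without ddx41 mutant replicate 4 and 0 without ddx41 mutant replicate 2. Ribosome biogenesis passed camera without sibling replicate 3 (adjusted p = 0.0211) or ddx41 mutant replicate 3 (0.0159), and ribosomal proteins without ddx41 mutant replicate 4 (0.000349). In the nonsense-mediated decay list, 2 of 14 genes rose and 1 fell, and EIF4A3, an exon junction complex helicase that the spliceosome list also holds, rose 4.08-fold. In the R-loop list, 3 of 22 genes rose and 3 fell, and AQR, an RNA helicase shared with the spliceosome list, rose 6.14-fold. Only 1 R-loop gene rose without sibling replicate 5, ddx41 mutant replicate 2 or ddx41 mutant replicate 3. These 4 lists did not pass camera (adjusted p 0.0956, 0.359, 0.53 and 0.359).

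In the apoptosis list 4 of 36 genes rose and 3 fell, and bbc3, which encodes the death-promoting protein Puma, rose 7.67-fold, from 5.57 to 42.7 CPM. That list did not pass camera (adjusted p = 0.382), and 1 gene rose without sibling replicate 1 or ddx41 mutant replicate 2, 2 rose without sibling replicate 3 or 4, and 5 fell without ddx41 mutant replicate 3. Outside it, mdm2, a ubiquitin ligase gene, rose 5.47-fold, from 85.9 ± 10.3 CPM (SD, n = 4) to 469.8 ± 115 CPM (SD, n = 3), and the exonuclease gene isg20 rose 3.31-fold. Among 43 DNA damage genes 5 rose and 3 fell (camera adjusted p = 0.786), and PRKDC, which encodes the catalytic subunit of DNA-dependent protein kinase, was 2.63-fold lower.

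Some genes of DNA replication rose and some genes of mitosis fell. Of 53 replication genes, 19 rose and 1 fell, with a median log2 fold change of 0.60, and 26 rose and 2 fell when adjusted over the list alone. The clamp loader gene RFC4 rose 5.98-fold, MCM10 rose 3.57-fold and ORC1, a subunit of the origin recognition complex, rose 3.55-fold. Of 47 mitosis genes, none rose and 23 fell, with a median of -0.65. TOP2A, the topoisomerase that separates sister chromatids, fell from 723.4 ± 35.7 CPM (SD, n = 4) to 296.7 ± 59.2 CPM (SD, n = 3). CDK1 was 2.45-fold lower and NUSAP1 2.35-fold lower. Camera gave adjusted p values of 2.79e-07 for replication and 1.22e-10 for mitosis, and with an estimated correlation the adjusted p values were 0.757 and 0.673. Without ddx41 mutant replicate 3, 11 replication genes rose and 3 fell, and 2 fell without sibling replicate 5. The number of mitosis genes that fell was 12 without ddx41 mutant replicate 2, 15 without sibling replicate 3 and 15 without sibling replicate 4. Among 28 genes of G1 cyclins, CDK inhibitors, RB and E2F, 8 rose and 3 fell (camera adjusted p = 0.359), and E2F7 rose 2.56-fold. In that list 5 rose without ddx41 mutant replicate 3, and 1 fell without ddx41 mutant replicate 2.

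Of 81 nuclear genes of oxidative phosphorylation, 43 rose and 1 fell, with a median log2 fold change of 0.71. COX4I1, a subunit of cytochrome c oxidase, rose 2.87-fold, from 244.7 ± 18.9 to 702.4 ± 79.2 CPM. The subunit genes atp5f1e and cox6c rose 2.54-fold and 2.42-fold. Of 13 transcripts of the mitochondrial genome, 10 rose and none fell, with a median of 0.83. MT-ND5 rose 2.06-fold, MT-ND2 2.05-fold and MT-ND3 1.92-fold. These 13 transcripts took 2.28% ± 0.246 of the counts in siblings (SD, n = 4) and 4.11% ± 0.686 in mutants (SD, n = 3; exact permutation p = 0.0286, two-sided, the smallest that 35 splits can give; 0.257 after Benjamini-Hochberg adjustment over 9 library measures). Camera gave adjusted p values of 5.4e-13 for the nuclear genes and 2.79e-07 for the mitochondrial genome, and with an estimated correlation the adjusted p values were 0.673 and 0.539. The number of nuclear genes that rose was 15 without ddx41 mutant replicate 2, 24 without sibling replicate 4 and 26 without sibling replicate 5. The number of mitochondrial transcripts that rose was 6 without sibling replicate 1. In the glycolysis list 5 of 29 genes rose and 1 fell (camera adjusted p = 0.334), and ALDOC, an aldolase gene, rose 4.59-fold. Glycolysis passed camera without ddx41 mutant replicate 3 (adjusted p = 0.0222), but 2 genes rose without sibling replicate 3 or 4, and 3 without sibling replicate 1 or 5. Without ddx41 mutant replicate 4, 2 glycolysis genes rose and 2 fell, with a median log2 fold change of -0.19. In the cholesterol synthesis list 4 of 28 rose and 1 fell (camera adjusted p = 0.359), and TM7SF2 rose 7-fold.

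Of 38 heat shock and chaperonin genes, 17 rose and 2 fell, with a median log2 fold change of 0.62. HSPB1, a small heat shock protein gene, rose 11.8-fold, the co-chaperone gene BAG3 rose 6.94-fold, and hsf1, which encodes the heat shock transcription factor, rose 4.47-fold. The most abundant members did not rise: hsp70.3, named here after its values were seen, fell from 4020 ± 635 CPM to 2417 ± 590 CPM (edgeR adjusted p = 0.0407). Camera gave the heat shock list an adjusted p of 4.74e-07, and the adjusted p was 0.539 with an estimated correlation. Without ddx41 mutant replicate 2, 10 members rose. The number of members that fell was 4 without ddx41 mutant replicate 3, and 1 without ddx41 mutant replicate 2 or any 1 of the siblings. Of 46 genes of the unfolded protein and integrated stress responses, 13 fell and 1 rose, with a median of -0.30. AARS1, an aminoacyl-tRNA synthetase gene, was 2.24-fold lower and mthfd2, of mitochondrial folate metabolism, was 2.33-fold lower, while the cystine transporter gene slc7a11 rose 2.28-fold. Without ddx41 mutant replicate 4 slc7a11 no longer passed edgeR's test (adjusted p = 0.0539). The camera adjusted p of the list was 0.00247, and the adjusted p was 0.539 with an estimated correlation. The number that fell was 3 without ddx41 mutant replicate 2, 6 without sibling replicate 1, 7 without sibling replicate 3 and 7 without sibling replicate 4.

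**Figure D1:**
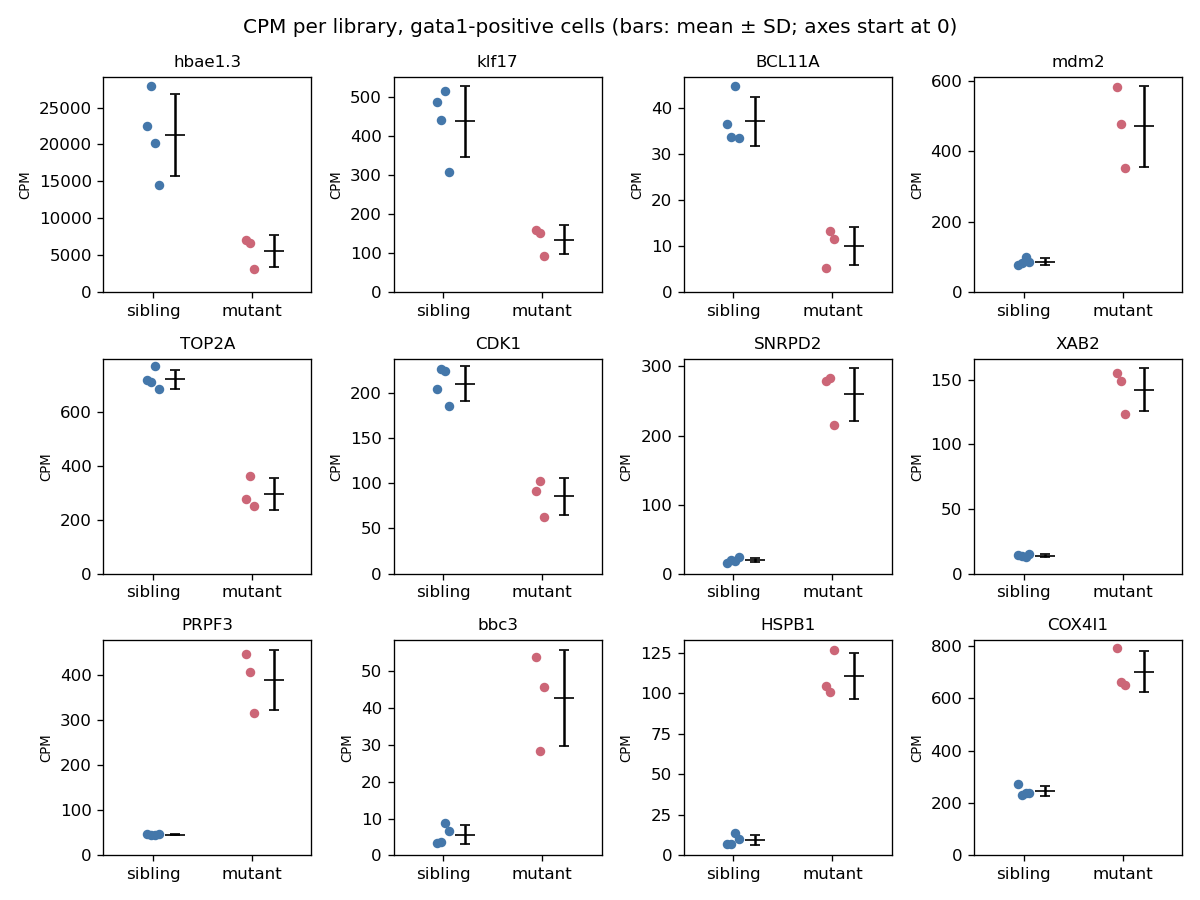
CPM of 12 named genes in each of the 4 sibling and 3 ddx41 mutant libraries, on linear axes that start at 0. Each point is a library and each bar a mean with its SD, and the groups do not overlap at any of these genes.

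Of 23 erythroid regulators, 6 fell and 2 rose, with a median log2 fold change of -0.43. The Krüppel-like factor gene klf17 fell from 437.1 ± 91.9 CPM (SD, n = 4) to 133.8 ± 37.4 CPM (SD, n = 3). BCL11A, a repressor known from globin switching, was 3.70-fold lower, and jak2a, a kinase of the erythropoietin pathway, was 2.08-fold lower. For the regulators the camera adjusted p was 0.00177, and the adjusted p was 0.673 with an estimated correlation. The 8 matched globin genes took 9.63% ± 1.83 of the counts in siblings (SD, n = 4) and 6.02% ± 2.4 in mutants (SD, n = 3), with an exact permutation p of 0.114 (two-sided). Of 14 globin symbols in the list 6, all of beta globins, were not matched to an ID. With the IDs called HBE1 added after the data were seen, the shares were 10.8% ± 1.79 in siblings and 6.46% ± 2.52 in mutants, and the groups did not overlap (exact permutation p = 0.0571, two-sided). The nearest libraries were ddx41 mutant replicate 2 at 8.839% and sibling replicate 5 at 8.873%. After Benjamini-Hochberg adjustment over 9 library measures, the permutation p was 0.342 for the 8 matched globins and 0.257 with HBE1. Of 8 tested globin genes 2 rose and 2 fell (camera adjusted p = 0.359), and the embryonic alpha globin gene hbae1.3 was 3.83-fold lower, at 21290 ± 5540 against 5563 ± 2160 CPM. Without ddx41 mutant replicate 2 no globin gene rose, 2 fell, and camera called the list lower (adjusted p = 0.0483). The number of globin genes that rose was 1 without any 1 of the siblings or without ddx41 mutant replicate 3. The number that fell was 1 without sibling replicate 1, 3 or 4 or ddx41 mutant replicate 3. Globin genes are near-identical copies, so the counting may divide their reads among them. Of 19 genes of haem synthesis and iron uptake 1 fell and none rose (camera adjusted p = 0.769), and 3 rose and none fell without ddx41 mutant replicate 4. That gene, the iron transporter gene slc11a2, was 1.62-fold lower with an edgeR adjusted p of 0.0464, and it no longer passed without sibling replicate 1, 3, 4 or 5 or without ddx41 mutant replicate 2 or 4 (adjusted p 0.0966, 0.105, 0.117, 0.0563, 0.082 and 0.102). Of 19 red cell membrane genes 2 rose and 2 fell (camera adjusted p = 0.272). SLC4A1 (ENSDARG00000024560), an anion exchanger gene, rose 3.77-fold from 51.8 CPM in siblings. It is 1 of 2 tested IDs with that symbol, named for its smaller p, so the fold is for this ID alone. The number of membrane genes that fell was 4 without ddx41 mutant replicate 3 and 1 without any other single library. Of 16 early blood progenitor genes 2 rose and none fell (camera adjusted p = 0.915), and hhex rose 4.62-fold, with an edgeR adjusted p of 0.106 without ddx41 mutant replicate 2. Without ddx41 mutant replicate 3, 3 progenitor genes rose and 2 fell, and without ddx41 mutant replicate 4, 1 rose and 1 fell.

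Markers of other cells were counted because a sort can carry them. Of 28 macrophage and pan-leukocyte markers, 9 fell and 1 rose, with a median log2 fold change of -0.62. Besides ccl34b.1, the macrophage gene MFAP4 (ENSDARG00000088745, 1 of 5 tested IDs with that symbol) was 5.81-fold lower. The cathepsin gene ctss2.2 was 3.31-fold lower. The camera adjusted p was 5.17e-05, and the adjusted p was 0.673 with an estimated correlation. The number that fell was 5 without ddx41 mutant replicate 2 and 15 without ddx41 mutant replicate 4. Of 30 skeletal muscle markers 8 fell and 3 rose, with a median of -0.97. The muscle genes actc1b and myhz2 were 3.10-fold and 4.52-fold lower. TTN (ENSDARG00000028213, 1 of 2 tested IDs with that symbol), the titin gene, rose 2.43-fold. The camera adjusted p was 0.0263, and the adjusted p was 0.757 with an estimated correlation. It was 0.0694 without sibling replicate 4, 0.127 without sibling replicate 5 and 0.0617 without ddx41 mutant replicate 4. The number of muscle markers that fell was 5 without each of sibling replicates 1, 4 and 5 and ddx41 mutant replicate 4, and 4 without ddx41 mutant replicate 2. The number that rose was 1 without sibling replicate 1 or 3 or ddx41 mutant replicate 2, and 4 without sibling replicate 5.

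The other 9 lists did not pass camera. In the neutrophil list 3 of 14 rose and none fell (adjusted p = 0.359), with ALOX5AP 2.29-fold higher (edgeR adjusted p = 0.0586 without ddx41 mutant replicate 4). The number of neutrophil markers that rose was 1 without sibling replicate 3 or 5, and without ddx41 mutant replicate 4 none rose and 1 fell. In the thrombocyte list 2 of 15 rose and 2 fell (0.359), with gp9 3.13-fold lower. The number of thrombocyte markers that fell was 3 without ddx41 mutant replicate 4 and 1 without any other single library, and 1 rose in 5 of these 7 cases. In the endothelial list 3 of 24 rose and none fell (0.0713), and the scavenger receptor gene stab2 rose 8.69-fold. The number of endothelial markers that rose was 1 without ddx41 mutant replicate 2 and 5 without ddx41 mutant replicate 3, and the list passed camera without sibling replicate 5 (0.0198) or ddx41 mutant replicate 3 (0.00569). In the neural list 3 of 34 fell and none rose (0.272), with FABP7 (ENSDARG00000007697) 7.42-fold lower. It passed camera as lower without ddx41 mutant replicate 4 (adjusted p = 0.000384, 6 lower), and 1 was lower without ddx41 mutant replicate 2. In the epidermis list 2 of 30 rose and 1 fell (0.63), and the keratin gene krt8 rose 2.26-fold, with 6 markers higher without sibling replicate 5 and 1 higher without sibling replicate 3 or 4 or ddx41 mutant replicate 2. In the yolk and liver list 2 of 20 rose and 2 fell (0.764), with apoa2 5.38-fold lower; 4 rose without sibling replicate 1 and none without ddx41 mutant replicate 2. In the lens and retina list 1 of 18 rose and 1 fell (0.786), and rlbp1b rose to 2.96 CPM from 0.168 CPM. In the pigment list 3 of 17 rose and 1 fell (0.58). DCT was 11.8-fold higher at low levels, 2.83 ± 1.09 CPM in mutants against 0.227 ± 0.296 CPM in siblings. Without ddx41 mutant replicate 3 the edgeR adjusted p of DCT was 0.0779, and in the pigment list none rose and 1 fell. In the interferon and innate immune list 6 of 40 fell and none rose (0.219), and the cytokine gene il1b was 2.07-fold lower. That count was 3 without each of sibling replicates 1 and 3 and ddx41 mutant replicates 2 and 3.

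In all, camera called 11 of 33 lists with the preset correlation, 6 higher and 5 lower, and none with an estimated correlation. The directional test fry called 5 lists, among them the spliceosome (adjusted p = 0.0101), mitochondrial genome (0.0151), heat shock (0.0151) and unfolded protein lists (0.0251). It did not call mitosis (0.051), nuclear oxidative phosphorylation (0.0655), erythroid regulators (0.0786), macrophage markers (0.0995), DNA replication (0.12) or skeletal muscle (0.215). Camera called between 5 and 18 lists when the same 7 libraries were divided in the 34 other ways, so the number of lists called did not stand apart from other divisions.

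**Figure D2:**
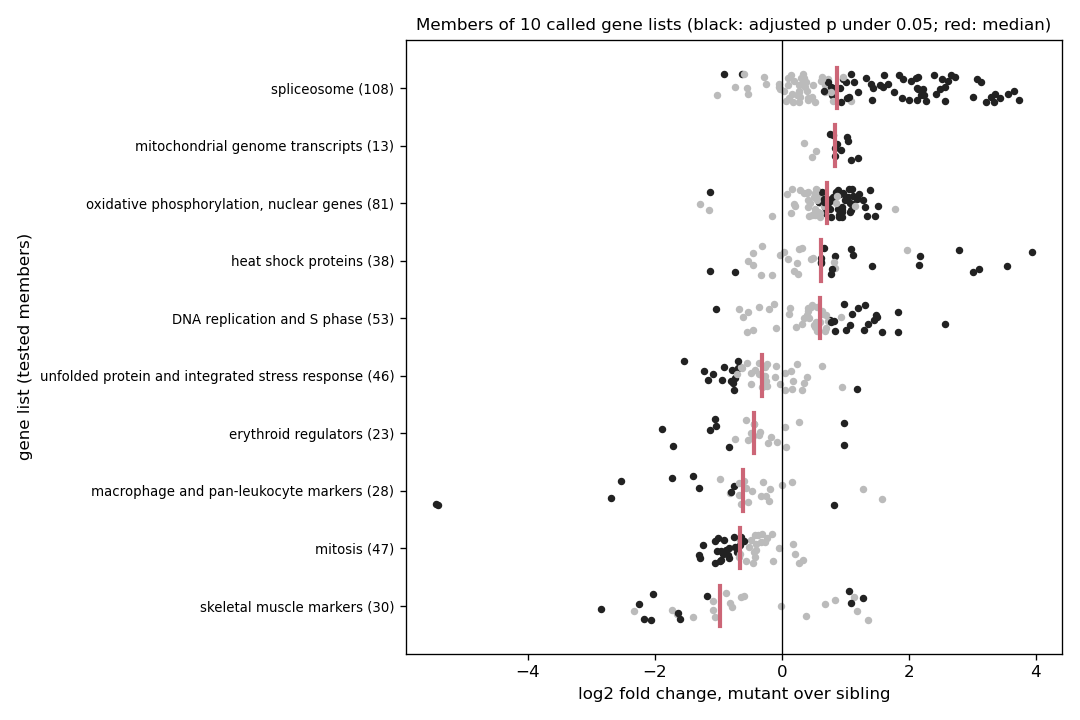
Log2 fold change of mutants over siblings for each tested member of 10 called lists, with members that passed edgeR's test in black, the others in grey and the median as a red line. The spliceosome list has the highest median, 0.87, and the skeletal muscle list the lowest, -0.97.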

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

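The tests of scaling, cycling cells, abundant heat shock members and macrophages in this part were chosen after the results were seen. In siblings, si:dkey-235h8.1 stood at 3.1 CPM in replicate 3 and between 11.97 and 13.63 CPM in the other 3 libraries, far enough apart to meet Dixon's criterion. Of 66 named genes and 9 library measures this was the only one to meet it in the 4 siblings, where chance flags about 1 in 20. Groups of 3 were not tested, so the mutants have no such check.

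Of 108 spliceosome transcripts 58 were higher in mutants, with a median log2 fold change above all 10000 random lists matched on expression. Random lists do not carry the correlation between members, estimated at 0.354. The list was lost with camera at that correlation and its fewer degrees of freedom (adjusted p = 0.539), and it passed fry (0.0101). Scaling or a few abundant transcripts would not single out this list, and at least 58 members were called higher under each of 5 scalings. More cycling cells would raise mitotic genes, whose median was -0.65, but more cells in S phase alone stay open, since the medians of DNA replication (0.60) and G1/S genes (0.466) were above 0. A rise of all RNA-processing transcripts would raise cleavage and polyadenylation genes, whose median was 0.195, and the gap between the lists separated the groups (exact permutation p = 0.0286, the smallest possible). An effect of the mutation itself, a developmental delay or a change in erythroid maturation stays open and was not tested.

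Of 38 heat shock transcripts 17 were higher in mutants and 2 lower. The list was lost with an estimated correlation (adjusted p = 0.539) but passed fry (0.0151). Stronger stress during dissociation and sorting would raise immediate early genes, but their median was -0.88, with 16 of 29 lower and none higher. A general heat shock response could raise its abundant members, and 0 of the 5 most abundant were called higher. Of these, hsp70l and hsp70.3 already stood at 5399 and 4020 CPM in siblings and may have had little room to rise. The 5 members therefore cannot exclude such a response. Less handling stress of the mutant cells could lower immediate early genes, and this was not tested apart from the median of -0.88. Why 17 members rose stays open.

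Of 28 macrophage markers 9 were lower in mutants, 1 was higher and 18 did not pass, and the list was lost with an estimated correlation (adjusted p = 0.673) and with fry (0.0995). An equal fall of all markers, which fewer macrophages alone would give, was not seen: the heterogeneity chi-square was 10.1 per degree of freedom over 28 markers, although the call of SPI1 as higher, chosen after its values were seen, was lost without sibling replicate 3 or 5 or ddx41 mutant replicate 4. A loss of macrophages as part of the change stays open, since erythroid cells may express some of these markers, and the value of 10.1 does not exclude it. Fewer cells of all other types among the mutant cells also stays open: such a fall would lower every list of other cells, and 1 of 9 such lists, the endothelial list, had members called higher and none lower with all libraries and with each library left out. This test was changed after values were seen. It first used 4 selected lists, of which 4 had a median above 0, and then all 9 with all libraries, of which 2 had members higher and none lower, and both versions argued against the explanation.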

How the results depend on the processing

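The scaling without mitochondrial transcripts and the 2 most abundant unnamed IDs, the exact symbol matches and the share with HBE1 were chosen after seeing the data. No named gene changed direction under any alternative run: over all alternatives, 1203 comparisons of a named gene with its main result kept their side of the threshold and 47 no longer passed. As the genes were named for small p or large folds in these same libraries, this was likely in advance. Of the 47, the replicate block gave 16 and the 4 libraries numbered 3 and 4 gave 19. With the block, edgeR adjusted p was 0.332 for MT-ND5, 0.287 for MT-ND2, 0.4 for MT-ND3, 0.103 for TOP2A and 0.0565 for NUSAP1. With the replicate block, 1023 genes were called (592 higher, 431 lower), 892 of them among the 3073, and the 4 libraries numbered 3 and 4 without the block called 822 (504 higher, 318 lower). Both use fewer libraries in effect. Whether the numbers pair the libraries is not known. Same-numbered libraries deviated from their group means with a correlation of -0.0163 for number 3 and -0.16 for number 4. Libraries with different numbers gave -0.143 to 0.236. With so few same-numbered libraries, these values cannot show whether a number marks a shared clutch or day. Leaving out 1 library gave 1888 to 2835 called genes, 1014 to 1471 higher and 874 to 1487 lower, 10 to 14 lists, and a globin difference of -4.761 to -2.367 percentage points. The lowest gene count came without ddx41 mutant replicate 2. The other scalings, filters and tests called 2975 to 3782 genes. Camera with an estimated correlation called 0 lists, where fry called 5. Among the called lists the estimated correlation ran from 0.0456 for the unfolded protein list to 0.644 for DNA replication. It was 0.354 for the spliceosome list. All lay above the preset of 0.01, and camera gives larger p-values at a higher correlation. With an estimated correlation camera also uses only the degrees of freedom left by the libraries, far fewer than with the preset. This too gives larger p-values, so the lost calls cannot be credited to the correlation alone. Why fry differed from camera was not tested. Camera lost the skeletal muscle call with 5 CPM in 3 libraries (adjusted p = 0.201), quality weights (0.0929), the replicate block (0.0959) and the 4 libraries alone (0.0832). Leaving out 1 library added endothelial, ribosome biogenesis, ribosomal protein, glycolysis, globin or neural calls. The replicate block added globin (0.00985), endothelial (0.0428) and epidermis calls (4.96e-08), and the 4 libraries alone added globin (0.00994) and epidermis calls (4.72e-06). The endothelial list was also called without a filter (0.0189), with DESeq2 (0.0178), with quality weights (0.0486) and with exact symbols (0.0239), and the weights added ribosomal protein (0.00528) and ribosome biogenesis calls (0.0102). The globin difference was -3.612 percentage points, and with HBE1 it was -4.307 (exact permutation p = 0.0571). Robust fitting does not apply to camera and was not run for lists, and no alternative was run for the ddx41 transcript. Simulated 2-fold changes in genes with a mean of at least 5 CPM were recovered at 38%. That simulation had 141 calls against 3073 in the data. Benjamini-Hochberg adjustment is stricter where fewer genes differ, so the 38% does not give the recovery in the data. Small changes can still be missed at this depth and number of libraries.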

Other observations

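The 6 lists in this part were written after the main results were seen but before their own values, except the division of the spliceosome list, which was made after its members were seen. Immediate early genes, which are induced within minutes of stimulation, were lower in mutants: 16 of 29 fell and none rose. NR4A1 fell from 125.3 to 34.9 CPM, egr1 from 345.1 to 183.2 CPM and IER5L from 31.98 to 10.07 CPM, all chosen after their values were seen.

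Within the spliceosome list, 47 of 73 members of the snRNPs and catalytic core rose and 1 fell, with a median log2 fold change of 1.55. Of 35 SR, hnRNP and other splice-site factors, 11 rose and 1 fell, with a median of 0.32. The difference between the class means was 1.1 log2 units larger in mutants and separated the groups (exact permutation p = 0.0286, the smallest possible). As the classes were drawn after the members were seen, this test does not decide whether the rise lies mainly in the snRNPs and the core.

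Because ice1 was among the largest rises named above, genes that make and process small nuclear RNA were tested without it. Their median was -0.0418, at percentile 33.55 of matched random lists, with 5 higher and 5 lower, so the list as a whole did not rise. The largest rise among them was that of the Pol III factor gene brf2, 10.8-fold, named after its value was seen. A list of genes for snRNP assembly and the R2TP chaperone complex had a median of 0.221, with 7 higher and 3 lower. Its percentile of 88.55 did not reach the 95th percentile set beforehand. The lower members were 2 IDs of MEPCE and TSC1 (ENSDARG00000057918), which are not assembly factors of spliceosomal snRNPs. The outcome is therefore for this mixed list, not for spliceosomal snRNP assembly alone.

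Cell cycle genes outside the fixed lists were tested next. Both lists were written after the mitosis and replication results were seen in the same libraries, so they give no independent check. Matched random lists do not carry the correlation between members. Genes of G2/M had a median of -0.585, below all matched random lists, with 17 of 42 lower and 1 higher, and their mean separated the groups (exact permutation p = 0.0286). Genes of G1/S had a median of 0.466, at percentile 99.78, with 7 of 24 higher and none lower, but their mean per library did not separate the groups (exact permutation p = 0.2). The percentile was the bound set beforehand, and by it alone the G1/S genes rose. The exact test of the library means was added to the rule for these 4 lists after the values were seen, and it left the G1/S genes undecided and changed no other of these outcomes. Fewer mutant cells in G2 or mitosis could give the fall in G2/M genes, with the median of -0.585, but counts per gene do not measure cell cycle phase.

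No window of neighbouring genes along the chromosomes stood out for large changes. With 12674 tested genes placed in the order of the GRCz12tu assembly, the densest window of 20 neighbours held 5 genes changed at least 4-fold, and shuffled genes reached this as often as not (permutation p = 0.536). The test was for linked sequence differences around a single locus, which would raise the highest window above that of shuffled genes (95th percentile 6). It left out those of the 18565 tested genes that were not placed, and changes under 4-fold. Looser clusters and the ddx41 locus by itself were not tested.

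For the number of genes called, only 1 of the 35 splits of the libraries, the real one, gave as many as 3073. The highest other split gave 0 in edgeR, with 155 to 3033 genes at an unadjusted p under 0.05. A share of 1 in 35 (0.0286) is the smallest that these splits can give. Every other split also puts mutants and siblings into the same group, which widens the spread there, so the 0 calls cannot exclude chance. Chance cannot be excluded for the number of lists: 27 of 35 splits called at least 11, and the highest other split called 18. List by list, 3 of the 33 had a camera p that no other split reached, the spliceosome and mitochondrial genome lists among them. Heat shock was reached by 2 of 35 splits, the real one included, the unfolded protein list by 3, mitosis by 4, erythroid regulators by 5, nuclear oxidative phosphorylation and macrophage markers by 8 each, DNA replication by 9 and skeletal muscle by 12. Other splits share mutants with the real one, so part of any difference carries into them.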
